A study of Mus musculus with 24 samples.

How the data were processed

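RNA-seq was analysed from 24 mouse liver libraries of strain C3H/HeJ. The titles give a genotype abbreviation (WT or TGA), a number from 1 to 4 and a suffix of 2, 4 or 8, and the genotype label reads wild type or transgenic. The 6 groups formed by genotype and suffix hold 4 libraries each. The labels do not say what the suffix means: it is called class 2, class 4 and class 8 here, and a reading as hepatocyte ploidy (DNA content) rests on the series title, not on a label. The transgene is not named in the labels either. Published work of this field used an shRNA against Anln, the gene of the cytokinesis protein anillin, and that it is the transgene here is a reading. Libraries that share a genotype and a number may come from one animal, which is also not stated. Nothing in the labels says that libraries of one group come from separate animals, so all p-values measure only the spread between these libraries, which may be technical.

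Per the labels' protocols, total RNA was purified with a kit for formalin-fixed, paraffin-embedded tissue, libraries were made with NuGen reagents, and all were sequenced together as single-end reads of 75 bp. Per the submitters' processing notes, TopHat, edgeR and the genome build mm9 were used. Their versions, the counting program, the annotation and the normalization are not given in the sources used here. No coordinates are printed, because the reference at hand is of another build, and genes are named by the symbols in the deposited table, of which 90.6% matched a current symbol list.

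The deposited table holds 35974 gene symbols and 24 columns of values on a natural log scale. The unit was inferred from the values, since no label states it. Quantile normalization replaces each value by the mean over all 24 libraries of the values at that rank, and at the lowest ranks above 0 only the 2 libraries with the most genes detected hold a count. In these libraries 942 and 655 genes sat (within 1e-09) at 2 times the natural log of 2, divided by 24, the level that a count of 1 gives there. The next levels, with 276 and 274 genes and with 143 and 230 genes, matched counts of 2 and 3. Above that the match ended: 86 and 0 genes sat at the level of a count of 4, and 0 and 2 at that of 5. The levels of 6, 7 and 8 held 0 genes in both libraries. The highest value was identical in 20 of the 24 libraries, as quantile normalization across libraries leaves it. The values were therefore read as the natural log of count + 1, quantile-normalised across libraries and averaged over the transcripts of each symbol. The averaging over transcripts is not shown by these levels and is a reading. The values were divided by the natural log of 2, so that every value below is log2(normalised count + 1). A difference on this scale can understate or overstate the change of genes with low values, because the most frequent value above 0 is high in libraries with few genes detected (20.8 normalised counts in TGA number 2 class 4). Read totals per library cannot be recovered from such values, so the sequencing depth is unknown, and no counting interval is given.

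The values are not counts, so the tests planned for counts were replaced by those planned for normalised values. Genes with a deposited value of at least 1 in at least 4 libraries were tested, which left 4875. limma (version 3.58.1, R version 4.3.3) was fitted with a mean-dependent prior (limma-trend) to all 24 libraries with 1 mean per group, and Benjamini-Hochberg adjustment was made over all genes tested, with a threshold of 0.05. The class comparisons average both genotypes. The genotype comparison over all classes used the mean of the 3 libraries of each genotype and number, 4 values against 4. In this fit the prior weighed as much as 152 degrees of freedom against 6 residual ones, and in the fit to 24 libraries 27.8 against 18. The pooled spread thus dominates the genotype test, and its smallest p-values rest on it. No covariate or block was used.

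Gene lists (34) were fixed before the data were examined, as were the groups, the tests, the alternatives to be tried and the rule for named genes. The 19 lists with at least 5 tested genes were tested with limma's camera at a preset correlation of 0.01 between genes, adjusted over the 19 lists within each comparison, and again with an estimated correlation and with fry. The mean of each list per library was also compared by two-sided exact permutation, a test chosen after the data were seen. Class labels were exchanged within genotype for the class comparisons over both genotypes (4900 assignments). For the interaction, genotype labels were exchanged within each class compared (4900 assignments). That exchange assumes no genotype difference within either class, so its p-values do not test the interaction alone. Comparisons of 4 against 4 cannot give a p under 0.0286. An adjusted p under 0.05 there would thus need at least 11 of the 19 lists at that value.

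The rule for named genes takes, for class 8 against 2, class 4 against 2 and TGA against WT per number, the 10 largest rises and 10 largest falls among genes past the threshold with a mean log2 value of at least 2. Class comparisons also require one direction in both genotypes, and the genotype comparison no overlap between the groups. The rule was written for log2 CPM and applied to the log2 values. Other comparisons take 3 rises and 3 falls. Where fewer than 5 genes pass, the 5 with the smallest p are named. The 3 members with the smallest p in the direction of each list called in the 3 main comparisons are named too, and Anln always. Some genes that the rule takes are not reported here. Where a gene past the threshold is listed at 0 in some libraries, their number is given in place of a mean and SD, because genes that every cell uses were also listed at 0.

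The procedure was tested on data made from the same 4875 genes, with libraries reassigned at random and shifts added to 200 genes. A log2 shift of 4 was recovered in 71.4% of cases for class 8 against 2 and 86.2% for TGA against WT per number. A shift of 2 was recovered in 15.0% and 27.7%. Among all calls in these made data, 4.48% and 2.11% were false. Without any shift, 20 reassignments gave at most 0 genes for class 8 against 2 and at most 11 for TGA against WT per number (median 0 in both), and camera called up to 5 and up to 8 lists (median 1 and 0). Libraries were reassigned singly, which separates the 3 libraries of each genotype and number. Shifts were added to values of 0 as well. The made data thus differ from the real ones, and these rates may be too favourable, above all for TGA against WT per number.

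Alternatives were a second quantile normalization, no filter on low values, only the groups compared, the number as a block, a pseudocount of 0.1, and leaving out each genotype and number in turn. Chosen after the data were seen were a robust prior, the log2 number of genes above 0 as a covariate, leaving out the 4 libraries with over 7000 genes above 0, and 2 stricter gene filters. Tests of counts were not run. Serpina1e, the Mup genes, ribosomal protein genes and small non-coding RNA genes have near-identical copies elsewhere in the genome, and how shared reads were assigned is not given in the sources used here, so their values are uncertain.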

Results

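Liver RNA was profiled in 24 libraries from wild-type (WT) and transgenic (TGA) mice of strain C3H/HeJ, with 4 libraries in each combination of genotype and class (2, 4 or 8). The series title concerns polyploid hepatocytes, the liver's parenchymal cells with more than the usual DNA content, in chronic liver disease. The comparisons the design implies are therefore between classes, between genotypes, and of the class difference between genotypes.

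The libraries differed widely in how much of the transcriptome they held. The number of genes with a value above 0 ran from 1624 in TGA number 2 class 4 to 15147 in WT number 1 class 2, out of 35974. Group medians were 5102, 3411 and 3175 genes for WT classes 2, 4 and 8 and 4328.5, 2650.5 and 2788.5 genes for the TGA classes. Of the values of the 4875 tested genes, 54.1% were 0. Genes used by every cell were also listed at 0: Actb (beta-actin) in 14 of 24 libraries, Gapdh (a glycolytic enzyme) in 19, Rplp0 (a ribosomal protein) in 17 and Eef1a1 (a translation elongation factor) in 5. A value of 0 thus does not show that a gene was silent. In TGA number 2 class 4, the most frequent value above 0 corresponded to 20.8 normalised counts, and in WT number 1 class 2 to 0.0595, so weakly expressed genes were detectable in few libraries. No libraries were duplicates: the highest correlation between 2 libraries was 0.767, across genes, which are not independent replicates, against a median of 0.317. That closest pair crossed the genotypes, being TGA number 2 class 2 and WT number 1 class 2.

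**Figure D1:**
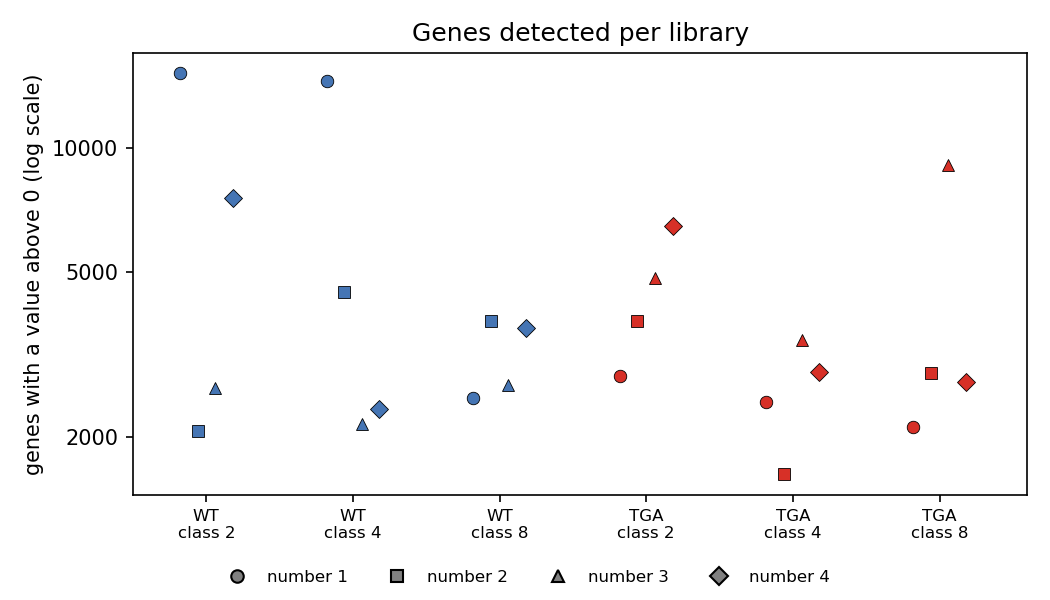
Number of genes with a value above 0 (log scale) in each of the 24 libraries, grouped by genotype and class; each point is 1 library and its shape gives the title number. WT number 1 stood at 15147 genes in class 2 and 14469 in class 4, while TGA number 2 class 4 had 1624.

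Anln was listed at 0 in all 12 TGA libraries and in 9 of 12 WT libraries, with log2 values of 0.06, 0.45 and 0.82 in the other 3. It did not reach the tested set, so it cannot check the genotype labels. Markers of other liver cells were hardly measurable. The macrophage and Kupffer cell, lymphocyte and erythroid lists had 0 tested genes, the neutrophil list 1, the cholangiocyte list 2 and the stellate cell and fibroblast list 3. The endothelial list, with 7 tested genes, was testable. Proliferation genes were near the floor too, with 4 tested genes for DNA replication, 2 for mitosis and 2 for cytokinesis and ploidy regulators. Fetal liver and liver cancer genes had 4 tested genes, core histone genes 3, nuclear long non-coding RNAs 4, interferon response genes 2, female-biased liver genes 1 and sex-chromosome transcripts 1. These 15 lists were not tested as lists.

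Class 8 was compared with class 2 over both genotypes. A single gene passed the threshold: Slc27a2, a very-long-chain acyl-CoA synthetase of liver, fell by 5.37 on the log2 scale (SE 1.06, adjusted p = 0.0369, limma). It was listed at 0 in 6 of 8 class 8 libraries and in 0 of 8 class 2 libraries. The next smallest p-values did not pass. Asl, the urea cycle enzyme argininosuccinate lyase, differed by -4.31 (SE 0.94) and Fam21, of the endosomal WASH complex, by -4.53 (SE 0.99), both with an adjusted p of 0.0607. Smarcd2, a chromatin remodelling subunit listed at 0 in 8 of 8 class 8 libraries, and Hip1r had an adjusted p of 0.192. Without adjustment, 63 genes were higher and 296 lower in class 8 at p under 0.05. The call of Slc27a2 was lost (0 genes) without WT number 1 or 3, or without TGA number 1, 2, 3 or 4, and without WT number 2 the 1 gene called was another. It was also lost (0 genes) with the number of genes detected as a covariate and with no filter on low values. Its log2 difference was between -7.84 and -5.01 over the 17 alternatives that tested it.

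Camera with its preset correlation called 5 lists lower in class 8 than in class 2, and 0 of them held with an estimated correlation, whose adjusted p follows each call. All 17 tested genes of fatty acid synthesis had lower values in class 8 (median log2 difference -1.66, camera adjusted p = 1.73e-05, and 0.485 with an estimated correlation), 0 of them past the threshold over all genes and 2 lower when adjusted over the list alone. Their leading members were Srebf1, the lipogenic transcription factor (-3.92), Acacb, an acetyl-CoA carboxylase (-3.27), and Aacs, acetoacetyl-CoA synthetase (-3.06). Periportal hepatocyte genes, which mark the zone near the portal vein, were lower for 19 of 22 (median -1.45, camera adjusted p = 0.000203, and 0.485 with an estimated correlation), led by Asl, Itih4 (-3.41) and Aldh1b1 (-2.47), with 0 over all genes and 1 adjusted over the list alone. Hepatocyte identity genes were lower for 22 of 26 (median -1.77, camera adjusted p = 0.00475, and 0.510 with an estimated correlation), with 0 past the threshold by either adjustment. Examples were Rbp4, the plasma retinol carrier (-3.01), Apoa2 (-2.80) and Ambp (-2.17). Male-biased liver genes were lower for 9 of 10 (median -1.44, camera adjusted p = 0.00724, and 0.510 with an estimated correlation; 0 by either adjustment), with Cyp2d9 at -2.53, Serpina1e at -2.52 and Mup20 at -2.25. ER stress genes were lower for 10 of 12 (median -1.28, camera adjusted p = 0.0466, and 0.510 with an estimated correlation; 0 over all genes and 1 adjusted over the list alone), with Dnajb9 at -2.77, Hspa5, the ER chaperone BiP, at -2.35 and Trib3 at -1.70. None of the members named here passed the threshold over all genes. The other 14 lists had camera adjusted p between 0.0536 (ribosomal proteins) and 0.915 (p53 targets). Among these 14, pericentral hepatocyte genes, of the other liver zone, also had a lower list mean (-0.48, exact permutation p = 0.0486, adjusted over 19 lists 0.154). The periportal list mean differed by -1.41 (exact permutation p = 0.0110, adjusted 0.112). Without TGA number 3, 3 lists were called, and 2 without the 4 libraries with over 7000 genes above 0. On data reassigned at random, camera called up to 5 lists for this comparison.

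Class 4 was compared with class 2 in the same way, and 15 genes fell while 0 rose (limma, adjusted p under 0.05). Vaultrc5, the RNA of vault particles, had the smallest p: it fell by 4.71 (SE 0.78, adjusted p = 0.0014) and was above 0 in 7 of 8 class 4 and 8 of 8 class 2 libraries. Snord17, a small nucleolar RNA, had a log2 difference of -5.40 (SE 1.28, adjusted p = 0.039). Among enzymes, Ftcd of histidine breakdown changed by -5.11 (SE 1.08, adjusted p = 0.0254), Slc27a2 by -4.72 (SE 1.06, adjusted p = 0.039) and Asl by -4.61 (SE 0.94, adjusted p = 0.0214). Srebf1 changed by -4.63 (adjusted p = 0.0482) and the stress-inducible gene Gadd45g by -5.08 (adjusted p = 0.039). Bms1, a ribosome assembly factor, Nav2 and Dcaf8 changed by -4.61, -4.61 and -4.46 (adjusted p = 0.039 each). The 9 genes other than Vaultrc5 were listed at 0 in 5 to 7 of 8 class 4 libraries and in 0 to 2 of 8 class 2 libraries. Without adjustment, 153 genes were higher and 510 lower. The count dropped to 2 without WT number 2, 1 without WT number 3, 7 without WT number 4, 2 without TGA number 1, 1 without TGA number 2, 2 without TGA number 3 and 5 without TGA number 4. It was 32, with 11 of the 15 genes among them, without the 4 libraries with over 7000 genes above 0, but 3 with the number of genes detected as a covariate and 0 with no filter on low values.

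Camera with its preset correlation called 5 lists for class 4 against 2, and 0 of them held with an estimated correlation. All 7 tested mitochondrial-encoded transcripts had higher values than in class 2 (median log2 difference 2.56, camera adjusted p = 5.55e-06, and 0.293 with an estimated correlation), 0 past the threshold over all genes and 5 adjusted over the list alone. These are subunits of the respiratory chain: ND4 differed by 4.04 (SE 1.34), ND6 by 2.76 (SE 1.13) and ND5 by 2.42 (SE 0.83). Their mean over the list was 10.05 ± 1.06 in WT class 4 and 8.31 ± 2.98 in TGA class 4, against 6.31 ± 1.85 and 6.87 ± 0.63 in class 2 (SD, n = 4 each). Fatty acid synthesis genes were lower for 16 of 17 (median -1.66, camera adjusted p = 6.92e-05, and 0.293 with an estimated correlation), with 1 past the threshold over all genes, Srebf1, and 5 adjusted over the list alone. Thrsp, a lipogenic regulator (-4.78), and Mlxipl, the carbohydrate-responsive transcription factor (-4.46), did not pass over all genes. Periportal genes were lower for 17 of 22 (median -2.01, camera adjusted p = 8.57e-05, and 0.293 with an estimated correlation), with 1 over all genes, Asl, and 8 adjusted over the list alone. Uroc1, of histidine breakdown, differed by -4.40 and Apoa4 by -4.23. Hepatocyte identity genes were lower for 22 of 26 (median -1.40, camera adjusted p = 0.00661, and 0.401 with an estimated correlation; 0 by either adjustment), with Proc, the anticoagulant protein C, at -3.41, Ttr, transthyretin, at -3.16 and Ambp at -3.02. ER stress genes were lower for 12 of 12 (median -1.42, camera adjusted p = 0.0364, and 0.350 with an estimated correlation; 0 over all genes and 2 adjusted over the list alone), with Herpud1 at -3.80, Sel1l at -1.92 and Trib3 at -1.62. The other 14 lists had camera adjusted p between 0.0745 (xenobiotic metabolism) and 0.891 (p53 targets).

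**Figure D2:**
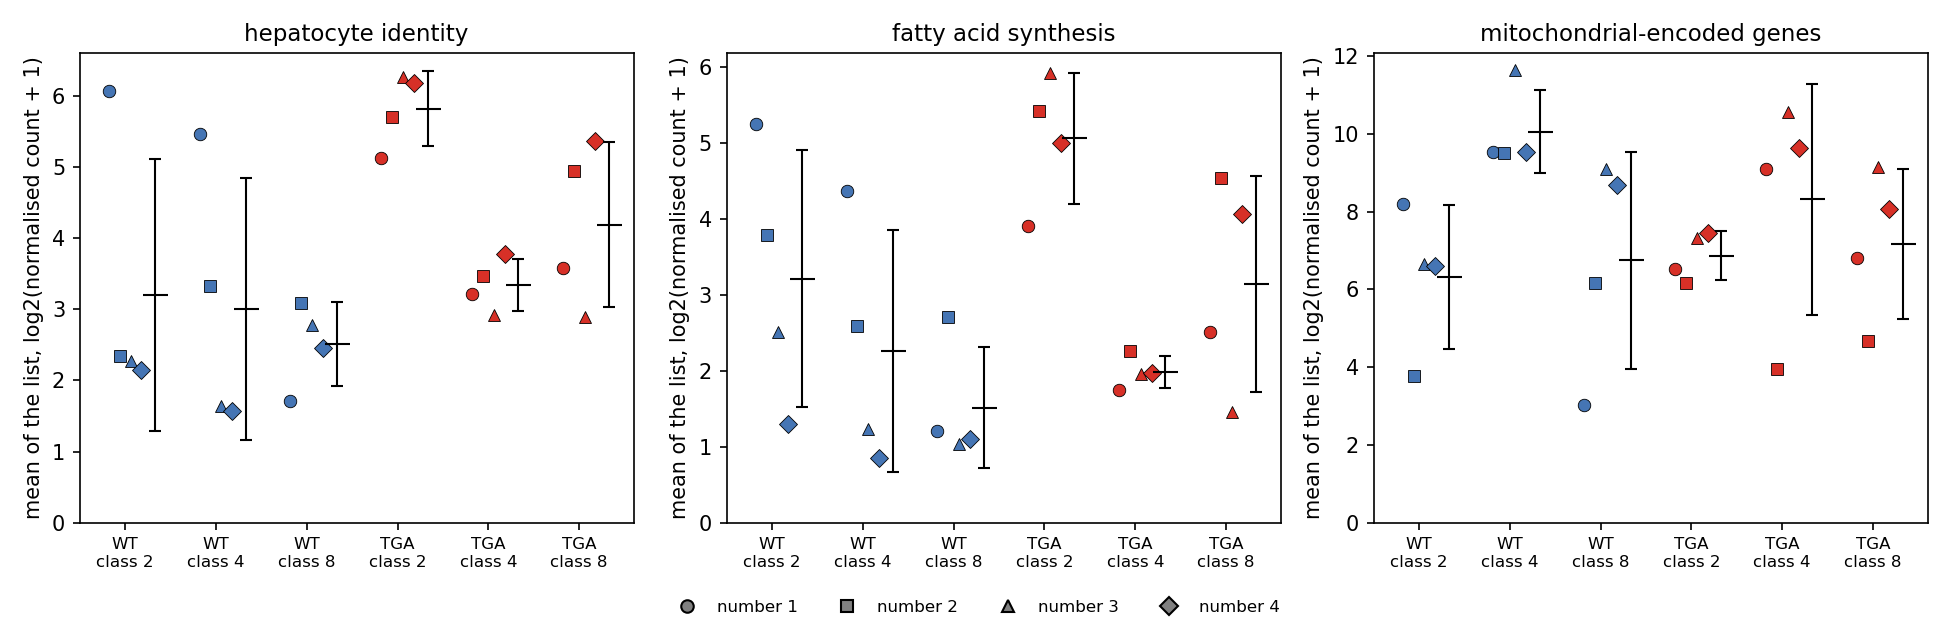
Mean log2(normalised count + 1) over the tested genes of 3 lists (hepatocyte identity, fatty acid synthesis and mitochondrial-encoded genes) in each library, by genotype and class; points are libraries, shapes give the title number, and the dash with bars is the mean ± SD of 4 libraries. Hepatocyte identity was highest in TGA class 2 (5.82 ± 0.52), and WT number 1 class 2 (6.07) lay above the other WT class 2 libraries (2.14 to 2.34).

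Between class 8 and class 4, 0 genes passed the threshold (limma), with 180 genes higher and 141 lower at an unadjusted p under 0.05. The 5 smallest p-values, all with an adjusted p of 0.718, belonged to Vaultrc5 (3.22), Aspg (4.39) and Cluh (3.96), with higher values in class 8, and to Kcnn3 (-3.38) and Myh13 (-3.65). Mitochondrial-encoded genes were lower in class 8 for 7 of 7 (median -2.02, camera adjusted p = 1.88e-05, and 0.402 with an estimated correlation; 0 over all genes and 3 adjusted over the list alone). No other list was called (camera adjusted p of 0.595 or more). The count of genes became 1 without WT number 1, 2 without TGA number 3 and 5 without the 4 libraries with over 7000 genes above 0.

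Within WT alone, class 8 against class 2 gave 0 genes past the threshold (237 at an unadjusted p under 0.05, limma). Gm33172, Gm34067, Fip1l1, Sec14l2 and LOC108169096 had the smallest p, with an adjusted p of 0.519. Sec14l2, a lipid-binding protein of liver, was listed at 0 in 4 of 4 WT class 8 libraries and in 0 of 4 WT class 2 libraries. Within TGA, 0 genes passed (348 unadjusted), and the 5 genes with the smallest p were listed at 0 in 4 of 4 class 8 and 0 of 4 class 2 libraries: Ndufb7, a respiratory complex subunit, Lrrc3, C1s1, a complement protease, Aacs and Pbld1 (adjusted p = 0.137). Fatty acid synthesis was the only list called in WT, lower for 17 of 17 genes (camera adjusted p = 0.00342). Its adjusted p was 0.834 with an estimated correlation, and none of its genes passed by either adjustment, over all genes or adjusted over the list alone (0 each). Without WT number 1 another list, with higher values, was called in its place, and 2 lists were called without WT number 2 or without WT number 4. In TGA, 6 lists were lower: periportal, hepatocyte identity, fatty acid synthesis, fatty acid oxidation, male-biased and ribosomal protein genes (camera adjusted p of 0.00123, 0.00243, 0.00243, 0.0176, 0.00355 and 0.0431). With an estimated correlation their adjusted p was 0.461 to 0.467. Of their genes, 0 passed over all genes, while adjusted over the list alone 3 male-biased genes, 1 of fatty acid synthesis and 1 of fatty acid oxidation passed. Without TGA number 3, 1 of the 6 remained, against 2 without the 4 libraries with over 7000 genes above 0. The class difference itself was tested between genotypes. The interaction gave 0 genes (198 unadjusted, limma) and 0 lists, and Aldh16a1, Sec14l2, C1s1 and Fbxl17, with the smallest p, had an adjusted p of 0.999. Without WT number 1, 1 list was called for the interaction.

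TGA was compared with WT over all classes, with 1 mean per genotype and number. In TGA, 12 genes rose and 12 fell (limma, adjusted p under 0.05). Other groupings of the same 8 means gave as many or more: 95 genes with WT number 1 and TGA number 1 exchanged, and 26 with WT number 1 and TGA numbers 1, 2 and 4 against the rest. Apoa1, the main protein of high-density lipoprotein, was 13.15 ± 0.85 in TGA and 9.44 ± 1.48 in WT (SD, n = 4; difference 3.71, SE 0.43, adjusted p = 2.73e-11). Alb, serum albumin, rose by 5.64 (SE 0.98, adjusted p = 8.2e-05) and was listed at 0 in 5 of 12 WT and 0 of 12 TGA libraries. Cps1, the entry enzyme of the urea cycle, rose by 4.66 (SE 0.97), Aldh1l1, of folate metabolism, by 4.94 (SE 1.05), Serpina1e, an alpha-1-antitrypsin, by 4.67 (SE 1.03) and Hyou1, an ER chaperone, by 4.70 (SE 1.09). These 4 were listed at 0 in 5, 4, 5 and 7 of 12 WT libraries and in 0 of 12 TGA libraries. Ptms, parathymosin, rose by 1.95 (SE 0.50). Mir6236, which held the highest value that the normalization allows in most libraries, rose by 0.64 (SE 0.12), a size limited by that ceiling. Rorb, a nuclear receptor known from retina and brain, fell from 13.31 ± 0.55 in WT to 9.44 ± 1.48 in TGA (SD, n = 4, difference -3.87, SE 0.42, adjusted p = 1.3e-12). Its mean over all libraries (11.38) was above those of Apoa1 (11.29) and Alb (6.68). Whether the reads counted for Rorb come from the mRNA of this receptor was not tested. Gm31305, an uncharacterised transcript, fell from 12.40 ± 0.60 to 10.05 ± 0.86 (adjusted p = 0.000118). The SEs rest mainly on the spread pooled over genes. For Apoa1, Alb, Aldh1l1, Serpina1e, Hyou1, Mir6236, Rorb and Gm31305 the SE is smaller than their own SDs would give, so their p-values overstate the certainty. The same holds for Ifit1, Vaultrc5, 4932431P20Rik, Trf and Selenbp2 below.

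Further falls in TGA were Arsb, a lysosomal sulfatase (-4.82), Ifit1, an interferon-induced gene (-3.96), Fgf9, a growth factor (-3.91), Sri, a calcium-binding protein (-3.90), Vaultrc5 (-2.94), 4932431P20Rik (-5.76), LOC105246707 (-4.52) and LOC108168402 (-4.05), with adjusted p between 0.000377 (4932431P20Rik) and 0.0486 (Sri). Of 12 TGA libraries, Fgf9 was listed at 0 in 9, 4932431P20Rik in 8, LOC105246707 in 3, Ifit1 in 2, and Arsb, Sri and Vaultrc5 in 1 each, and of 12 WT libraries each of these in 0. The named genes were those without overlap between the 4 numbers of each genotype, which chance gives for 2.86% of genes. Without adjustment, 178 genes were higher and 255 lower in TGA. WT number 1 differed from the other WT numbers: without it 95 genes passed, the 24 among them. The count was 13 without WT number 2, 14 without WT number 3, 10 without WT number 4 and 13 without TGA number 4, and 84 without the 4 libraries with over 7000 genes above 0. It was 42, with 23 of the 24 genes among them, with the number of genes detected as a covariate, and 9 with no filter on low values.

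**Figure D3:**
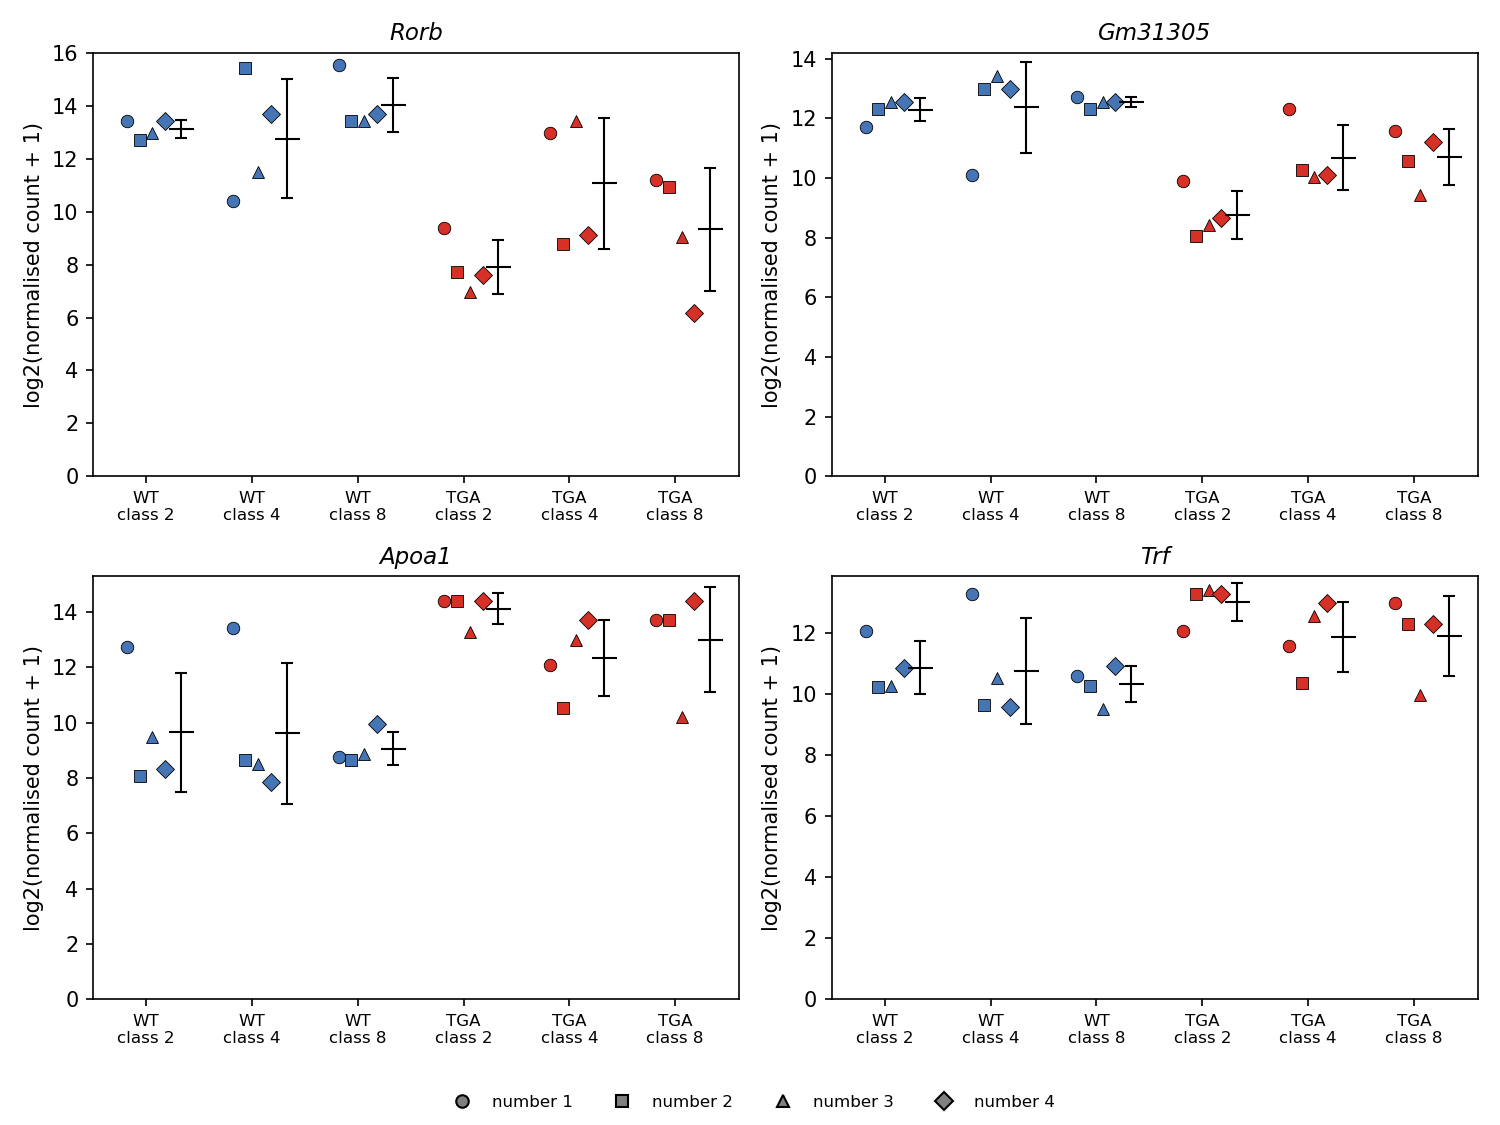
Values of Rorb, Gm31305, Apoa1 and Trf, as log2(normalised count + 1), in each library by genotype and class; points are libraries, shapes give the title number, and the dash with bars is the mean ± SD of 4 libraries. Rorb was 13.14 ± 0.34 in WT class 2 and 7.92 ± 1.03 in TGA class 2, and Apoa1 9.65 ± 2.14 and 14.12 ± 0.56.

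Camera with its preset correlation called 8 lists higher in TGA, and 0 of them held with an estimated correlation. Hepatocyte identity genes were higher for 24 of 26 (median log2 difference 1.62, camera adjusted p = 8.5e-09, and 0.346 with an estimated correlation), 3 of them past the threshold over all genes (Apoa1, Alb and Trf, the iron carrier transferrin, at 1.61) and 5 adjusted over the list alone. Male-biased genes were higher for 10 of 10 (median 1.39, camera adjusted p = 1.98e-05, and 0.346 with an estimated correlation; 2 over all genes, Serpina1e and Selenbp2 at 4.52, the latter listed at 0 in 7 of 12 WT and 1 of 12 TGA libraries, and 3 adjusted over the list alone), with C8a, a complement component, as a further example. ER stress genes were higher for 11 of 12 (median 1.12, camera adjusted p = 0.000503, and 0.346 with an estimated correlation; 1 over all genes, Hyou1, and 3 adjusted over the list alone), with Hsp90b1 at 3.36 and Hspa5 at 3.06. Ribosomal protein genes were higher for 13 of 15 (median 1.12, camera adjusted p = 0.0032, and 0.346 with an estimated correlation; 0 by either adjustment), with Rpsa at 3.18, Rpl8 at 1.91 and Rplp1 at 1.65. Fatty acid synthesis was higher for 14 of 17 (median 1.08, camera adjusted p = 0.0082, and 0.445 with an estimated correlation; 0 over all genes and 1 adjusted over the list alone), with Fasn, fatty acid synthase, at 3.40 and Gpam at 2.21. Acute phase genes were higher for 10 of 12 (camera adjusted p = 0.0238, and 0.346 with an estimated correlation), with Itih3 at 3.06, Fga, a fibrinogen chain, at 2.10 and Hp, haptoglobin, at 2.07. Nuclear-encoded oxidative phosphorylation genes were higher for 7 of 8 (camera adjusted p = 0.0297, and 0.346 with an estimated correlation), with Atp5a1 at 2.81, Ndufb9 at 1.79 and Ndufv1 at 1.65. Both of these lists had 0 genes past the threshold by either adjustment, over all genes or adjusted over the list alone. Periportal genes were higher for 18 of 22 (camera adjusted p = 0.0345, and 0.445 with an estimated correlation), with Cps1 higher and Pigr, the immunoglobulin transporter (-1.61, named after its values were seen), lower over all genes, 3 higher and 1 lower adjusted over the list alone, and Cyp2f2 at 3.14.

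The mean of the hepatocyte identity list differed by 1.55 between the genotypes over the 4 numbers each (exact permutation p = 0.0857, adjusted over 19 lists 0.271). Without WT number 4, 4 lists were called. On data reassigned at random, camera called up to 8 lists in this comparison. The endothelial list had lower values in TGA for 5 of 7 genes (median -0.55), without passing in camera (adjusted p = 0.0839). The other 11 lists, this one included, had camera adjusted p of 0.0839 to 0.790 (tumour suppressors).

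The genotypes were also compared within each class, 4 libraries against 4. In class 2, 5 genes passed (425 unadjusted, limma). Apoa1 rose by 4.47 (SE 0.89, adjusted p = 0.0147), while Rorb fell by 5.22 (SE 0.92, adjusted p = 0.00385), LOC108168367 by 6.37 (SE 1.35, adjusted p = 0.0273; at 0 in 1 of 4 TGA and 0 of 4 WT libraries) and Arsb by 6.31 (SE 1.37, adjusted p = 0.0329). Gm31305, named after its values were seen, also fell. After a second quantile normalization 3 genes were higher and 6 lower. The count was 50 without WT number 1, 1 without WT number 2, 2 without WT number 3, 0 without WT number 4, 8 without TGA number 1, 2 without TGA number 2 and 2 without TGA number 4. In class 4, Mir6236 alone passed (1.83, SE 0.37, adjusted p = 0.0471, limma; 207 genes unadjusted). All 4 TGA libraries held the highest value that the normalization allows (16.41), so neither the size nor the spread in TGA can be measured there. Mir6236 lost the call without any 1 of the numbers other than WT number 1, where 9 genes passed. Vaultrc5 (-4.70), 4932431P20Rik (-5.86), Kcna2 (-4.98) and Galnt13 (-2.86) did not pass. In class 8, Rorb alone passed, falling by 4.69 (SE 0.92, adjusted p = 0.0289, limma; 476 genes unadjusted). Arsb (-6.13), Apoa1 (3.95), Cylc2 (-5.37) and Gm33172 (-2.68) did not pass (adjusted p of 0.0937 to 0.105). The count in class 8 was 14 without WT number 2, 4 without WT number 4, 2 without WT number 3, TGA number 1 or TGA number 3, and 0 without TGA number 4. Without WT number 1, 1 gene other than Rorb passed.

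Camera called 9 lists higher in TGA in class 2, 0 in class 4 and 4 in class 8. In class 2 these were hepatocyte identity, male-biased, ER stress, ribosomal protein, fatty acid synthesis, periportal, fatty acid oxidation, nuclear-encoded oxidative phosphorylation and acute phase genes, with adjusted p from 5.48e-08 (hepatocyte identity) to 0.0172 (acute phase). With an estimated correlation their adjusted p was between 0.128 and 0.313. Over all genes 1 member passed, Apoa1; adjusted over the list alone, 10 hepatocyte identity, 5 male-biased, 2 ER stress and 1 fatty acid oxidation gene were higher, and 1 periportal gene was higher and 1 lower. In class 8 the lists were hepatocyte identity, ER stress, male-biased and fatty acid synthesis genes, with adjusted p of 0.00212, 0.00884, 0.0144 and 0.0144. All 4 had an adjusted p of 0.335 with an estimated correlation. In class 8, 0 members passed over all genes, and adjusted over the list alone 3 hepatocyte identity, 3 male-biased and 1 ER stress gene were higher. Without TGA number 4, 2 lists were called in class 8, and in class 4, 1 list was called without WT number 1 and 1 without TGA number 3. Hepatocyte identity means were 5.82 ± 0.52, 3.34 ± 0.36 and 4.19 ± 1.15 in TGA classes 2, 4 and 8 and 3.20 ± 1.91 and 2.51 ± 0.59 in WT classes 2 and 8 (SD, n = 4 each), with 1.56 to 5.47 in WT class 4. WT number 1 class 2 (6.07) and WT number 1 class 4 (5.47), both among the libraries with the most genes detected, lay within or near the TGA class 2 range of 5.12 to 6.27.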

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

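Tests of small non-coding RNAs, of unequal detection as the whole cause and of exchanged labels were chosen after the result was seen, as were the contrasts that pool classes, the list means and the genes to which the check for libraries far from their group was applied; the other tests of explanations were written before their results. In 113 groups of 4 libraries, the library farthest from the others was compared with the spread of its group, and 21 stood apart. Chance flags about 1 in 20 groups, but in 5 of the 21 the other 3 libraries were identical, where any library that differs stands apart and this rate does not apply.

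WT number 1 stood apart in class 2 by its list means: hepatocyte identity was 6.07 (other libraries of the group 2.14 to 2.34), ER stress 4.40 (0.99 to 1.51), male-biased liver genes 4.08 (0.60 to 1.05) and nuclear-encoded oxidative phosphorylation 3.59 (0 to 0.33). In class 4, WT number 1 had a ribosomal protein mean of 2.87 (0.59 to 0.89), Apoa1 at 13.42 (7.87 to 8.65) and Gm31305 at 10.10 (12.98 to 13.42). In class 8, it had nuclear-encoded oxidative phosphorylation at 1.38 (others 0), Mir6236 at 14.32 (others 16.41) and Rorb at 15.54 (13.42 to 13.71). Other WT libraries that stood apart were number 2 class 8 in fatty acid synthesis (2.71, others 1.04 to 1.20), number 3 class 4 in mitochondrial-encoded genes (11.65, others 9.50 to 9.53), number 4 class 8 in Apoa1 (9.95, others 8.67 to 8.86) and number 2 class 2 in Mir6236 (15.54, others 16.41).

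Among TGA libraries, number 3 class 8 had 9096 genes above 0 (others 2110 to 2860), Apoa1 at 10.19 (13.71 to 14.40) and Mir6236 at 15.54 (others 16.41). TGA number 3 class 2 had Apoa1 at 13.27 (others 14.40). TGA number 4 class 4 had Ptms at 12.73 (10.06 to 10.36), TGA number 1 class 4 had Gm31305 at 12.32 (10.04 to 10.28), and TGA number 1 class 2 had Trf at 12.08 (13.27 to 13.42).

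Hepatocyte identity genes had higher values in TGA than in WT, by 1.55 in the mean over the list (two-sided exact permutation p = 0.0857, adjusted over 19 lists 0.271, 4 numbers against 4). In a linear fit to the 8 means with the number of genes detected as a covariate, the difference was 1.76 (95% interval 0.36 to 3.16). This argues against unequal detection as the whole cause only as far as that fit holds. It rests on 8 values, among which WT number 1 stands apart in detection (15147 and 14469 genes in classes 2 and 4). That unequal detection made up part of the difference stays open, because the interval reaches below 0.5 times 1.55. The percentage of the list's genes above 0, which quantile normalization cannot change, differed by 16.3 points (exact permutation p = 0.114), and small non-coding RNAs by -0.72 (exact permutation p = 0.4), which leaves an effect of the normalization and a loss of mRNA open. The transgene, as a biological explanation, also stays open and was not tested apart from these.

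Hepatocyte identity genes had lower values in classes 4 and 8 than in class 2, by -1.25 (two-sided exact permutation p = 0.0303, not adjusted). Neither class alone passed by exact permutation (class 4 p = 0.0931, adjusted over 19 lists 0.177, and class 8 p = 0.0657, adjusted 0.169). Class 8 against 2 gave -1.63 in TGA (exact permutation p = 0.0571) and -0.70 in WT (exact permutation p = 0.8). The fall in WT rested on number 1, at 6.07, 5.47 and 1.70 in classes 2, 4 and 8. WT numbers 2 to 4 lay at 2.14 to 2.34, 1.56 to 3.33 and 2.46 to 3.08. Loss of mRNA with small non-coding RNA taking its place needs those RNAs higher, and they differed by -1.87 over both classes (exact permutation p = 0.005). In class 4 they went the other way from what that form of mRNA loss needs (-2.70, exact permutation p = 0.00122). The set was formed after Vaultrc5 and Snord17 were called lower there and holds both, so it cannot decide against that loss. Such a loss stays open in class 4 and in class 8 (-1.04, exact permutation p = 0.128). Other forms of mRNA loss were not tested, and these differences were not adjusted for the number of genes detected. Unequal detection stays open, as the whole cause or part of it: with the number of genes detected as a covariate the difference was -0.83 (95% interval -1.80 to 0.15). An effect of the quantile normalization stays open as well, the percentage of list genes above 0 differing by -16.3 points (exact permutation p = 0.0797), and so does what the classes stand for in biology, which was not tested.

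Mitochondrial-encoded genes had higher values in class 4 than in classes 2 and 8, by 2.41 (two-sided exact permutation p = 0.0112, not adjusted), but neither comparison alone passed when adjusted over 19 lists (against class 2 p = 0.0176, adjusted 0.0814; against class 8 p = 0.0743, adjusted 0.477; exact permutation). A single title number as the cause is argued against, because the difference stayed between 2.22 and 2.87 when each genotype and number was left out in turn. With the number of genes detected as a covariate it was 2.64 (95% interval 0.93 to 4.35), which argues against unequal detection as the whole cause; apart, this holds against class 2 (3.02, 0.99 to 5.05) and stays open against class 8 (2.24, -0.23 to 4.71), and detection as part of the cause stays open in both. The percentage of list genes above 0 differed by 4.46 points (exact permutation p = 0.549), so an effect of the normalization on genes detected nearly everywhere stays open. Small non-coding RNAs moved the other way, by -2.70 in class 4 against 2 (exact permutation p = 0.00122) and by 1.66 in class 8 against 4 (exact permutation p = 0.018). Whether these shifts are linked was not tested. A difference between the classes themselves was not tested apart from these explanations and is open too.

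Other splits of the same libraries were fitted in the same way. For class 4 against 2, 1 of 100 splits (the real one) gave as many genes, 15 against at most 7. This share, under the 0.05 set beforehand, argues against chance. It does not exclude chance, because the splits were a random sample and several comparisons were examined. For class 8 against 2, 4 of 100 splits gave as many genes, a share under 0.05. With 1 gene in the real split and 1 in the highest of the others, the count itself does not stand above other groupings. For TGA against WT per number chance was not excluded: 3 of 35 splits gave as many as the real 24. The split that exchanges WT number 1 and TGA number 1 gave 95, which points to a structure of the samples, and WT number 1 with TGA numbers 1, 2 and 4 gave 26. Within class 2, 2 of 35 splits gave as many as the real 5 (at most 12), within class 4, 8 of 35 as many as the real 1 (at most 12), and within class 8, 2 of 35 as many as the real 1 (at most 1), so chance was not excluded in any class. Where the real count was 0 it cannot be exceeded from below: all 100 splits for class 8 against 4 (at most 5 in the others) and for the interaction (at most 16), all 35 within WT and all 35 within TGA (at most 1 in each) gave as many.

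Whether the labels of the samples numbered 1 were exchanged was tested on 64 genes called from numbers 2 to 4 alone, with the WT mean set to 0 and the TGA mean to 1. An exchange needs WT number 1 above the midpoint of 0.5 and TGA number 1 below it, each by more than the spread of the other numbers (SD 0.220, from smaller sets of 10, 6 and 7 genes called without each of these in turn). WT number 1 lay at 0.649 (0.750, 1.40 and -0.0864 in classes 2, 4 and 8) and TGA number 1 at 0.596 (0.709, 0.467 and 0.566), with the other numbers, on those smaller sets, at -0.265 to 0.144 in WT and 0.904 to 1.32 in TGA. WT number 1 lay toward TGA where many genes were above 0 (15147 in class 2 and 14469 in class 4), not in class 8 (2479). TGA number 1, with 2816, 2434 and 2110 genes, lay between the genotypes in each class. An exchange stays open, as do a wrong label on single libraries and a mixture. An effect of unequal detection on these positions was not tested and is open too. The results for TGA against WT thus hold only if the labels are right. Rorb was 13.12 in WT number 1 and 11.19 in TGA number 1, but it was named for not overlapping between the labelled genotypes and cannot decide it.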

How the results depend on the processing

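The robust prior, the covariate, the fit without the 4 libraries with over 7000 genes above 0, both stricter filters and the exact permutation of list means were chosen after the data were seen. No named gene reversed, nor did any of the 18 lists called for class 8 against 2, class 4 against 2 and TGA against WT per number. Of 1923 combinations of a named gene and an alternative, 1652 stayed on their side of the threshold, 225 lost the call and 46 gained it. Many named genes were not called at first and had no call to lose, so all losses fall on the called genes. For class 4 against 2, Srebf1, Bms1, Nav2 and Dcaf8 each lost the call under 12 of 17 alternatives. Vaultrc5 lost it there under 1 of 18. Of 363 combinations for these 18 lists, 265 kept and 98 lost the call. Alb, Apoa1, Rorb, Gm31305 and 4932431P20Rik in TGA against WT per number were called under each alternative that tested them. The cause was not tested for any of the changes that follow. Counts that moved by more than 1.5 times are given, and numbers of genes come before numbers of lists. DESeq2, limma-voom, RLE factors, upper-quartile factors and a 5-per-million filter were planned and not run, because the values are not counts. Sequencing depth is unknown, and 54.1% of the values of tested genes are 0, so small changes of weakly expressed genes were not detectable.

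With a second quantile normalization, genes numbered 0 for class 8 against 2, and for TGA against WT 9 in class 2, 3 in class 4 and 2 in class 8. With no low-value filter (21390 genes tested), they numbered 0 for class 8 against 2, 0 for class 4 against 2, 9 for TGA against WT per number and 0 in each of classes 2, 4 and 8, and lists numbered 8 for class 4 against 2, 0 for class 8 against 2 in WT and 10 in TGA. With only the groups compared in the fit, genes for TGA against WT numbered 0 in class 4 and 4 in class 8, and 1 list was called in class 4. With a pseudocount of 0.1, genes numbered 0 for class 8 against 2, 25 for class 4 against 2 and 3 for TGA against WT in class 2, and 7 lists were called in class 8. With a robust prior, genes numbered 0 for class 8 against 2, 4 for class 4 against 2 and 0 for TGA against WT in class 4.

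With the number of genes detected as a covariate, genes numbered 0 for class 8 against 2, 3 for class 4 against 2, 42 for TGA against WT per number and 0 in class 4 and in class 8, and lists numbered 2 for class 8 against 2 and 3 for class 4 against 2. Without the 4 libraries with over 7000 genes above 0, genes numbered 32 for class 4 against 2, 5 for class 8 against 4, 1 for class 8 against 2 in WT, 84 for TGA against WT per number, 7 in class 4 and 10 in class 8, and lists 2 for class 8 against 2, 2 for class 8 against 2 in TGA and 1 for TGA against WT in class 4. For genes above 0 in at least 20 libraries, fewer of which exist, genes numbered 0 for class 8 against 2, 7 for class 4 against 2, and for TGA against WT 17 in class 2, 0 in class 4 and 9 in class 8, while lists numbered 1 for class 8 against 2, 1 for class 4 against 2, 0 for class 8 against 2 in WT, 1 in TGA, and for TGA against WT 1 per number, 1 in class 2 and 1 in class 8. For a value of at least 2 in at least 8 libraries, genes numbered 3 for class 8 against 2, 39 for class 4 against 2, and for TGA against WT 0 in class 4 and 2 in class 8, while lists numbered 3 for class 8 against 2, 3 for class 4 against 2, 3 for class 8 against 2 in TGA, and for TGA against WT 3 per number, 1 in class 2 and 2 in class 8.

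The list tests with an estimated correlation and the exact permutation of list means each called 0 lists for class 8 against 2, class 4 against 2, class 8 against 4, class 8 against 2 in WT and in TGA, and TGA against WT per number, in class 2 and in class 8. In comparisons of 4 against 4, the permutation would need at least 11 lists at its smallest p to call any, so its losses there say little. The test by fry called 0 lists for class 8 against 2, class 8 against 4, class 8 against 2 in WT and in TGA, and TGA against WT per number and in class 8, 5 in class 2 and 1 in class 4. For class 4 against 2 it called 5 lists, 2 of them among the 5 that camera called.

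Leaving out each genotype and number in turn gave, for genes, 0 to 1 for class 8 against 2, 1 to 20 for class 4 against 2, 0 to 2 for class 8 against 4, 10 to 95 for TGA against WT per number, 0 to 50 in class 2, 0 to 9 in class 4 and 0 to 14 in class 8. For class 8 against 2 in WT, in TGA and for the interaction it gave 0 throughout. For lists it gave 3 to 6 for class 8 against 2, 4 to 6 for class 4 against 2, 1 for class 8 against 4, 1 to 2 for class 8 against 2 in WT, 1 to 6 in TGA and 0 to 1 for the interaction, and for TGA against WT 4 to 10 per number, 7 to 9 in class 2, 0 to 1 in class 4 and 2 to 6 in class 8. The highest values per number (95) and in class 2 (50) were those without WT number 1.

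The title numbers did not meet the rule for pairing, which needs each pair of one number to correlate above 0.1. Deviations of libraries of one genotype and number correlated at -0.10 to 0.43 across genes, which are not independent replicates (median 0.03, against -0.01 for other numbers), above 0.1 in 2 of 24 pairs. Of 24 libraries 12 correlated best with one of their own number, where chance gives 6, so some pairing is not ruled out. With the number as a replicate block, genes numbered 23 for class 4 against 2 and 2 for TGA against WT in class 8, and no other count moved by over 1.5 times. For class comparisons the block was each genotype and number. For genotype comparisons it joined WT and TGA libraries of one number, which no label relates. Deviations of libraries of one number from different genotypes had a median correlation of -0.0004.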

Other observations

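All of the groupings below were chosen after the data were seen, except the endothelial list, which was fixed before. Small non-coding RNAs, 22 of them above the limit for testing, were lower in class 4 than in class 2 in 22 of 22 genes, with a mean difference of -2.70 (two-sided exact permutation p = 0.00122). They include Rn7sk, which holds back transcription elongation (9.10 in class 2, 4.80 in class 4 and 6.93 in class 8), Rpph1, the RNA of RNase P (12.96, 11.24 and 12.45), Rmrp, of the related RNase MRP (9.52, 8.43 and 9.16), and Snord15a, a small nucleolar RNA (8.91, 6.52 and 8.85). Class 8 lay above class 4 for these RNAs by 1.66 (exact permutation p = 0.018), with 0 of 22 lower, and below class 2 by -1.04 (exact permutation p = 0.128), with 19 of 22 lower. Their mean over all 22 was 5.62 ± 1.43, 3.37 ± 1.36 and 5.20 ± 1.63 in WT classes 2, 4 and 8 and 5.62 ± 0.46, 2.48 ± 0.33 and 3.96 ± 1.24 in TGA (SD, n = 4 each). The class 8 against 2 difference was not shown to differ between genotypes (interaction -1.24, exact permutation of genotype labels within class, p = 0.355). These are 10 comparisons, whose p-values were not adjusted.

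Markers of endothelial cells, which line the sinusoids, were 0.47 ± 0.18 in TGA and 0.98 ± 0.18 in WT (mean over 7 genes, SD, n = 4 numbers each). The difference of -0.50 had a two-sided exact permutation p of 0.0286, the smallest that 4 against 4 can give, and 0.271 adjusted over 19 lists, where under 0.05 would need at least 11 lists at that smallest p. Erg, an endothelial transcription factor, differed by -1.68, Bmp2 by -0.85 and Stab2, a scavenger receptor of sinusoids, by -0.66, while Kdr, a VEGF receptor, differed by 0.70. Means by class were 0.66 ± 0.28, 1.39 ± 0.47 and 0.89 ± 0.47 in WT and 0.76 ± 0.31, 0.52 ± 0.40 and 0.14 ± 0.17 in TGA classes 2, 4 and 8 (SD, n = 4 each). These means lie near the floor. The list mean was 0 in TGA number 3 class 4 and in TGA numbers 1 and 2 class 8, while the lowest in WT was 0.44. A value of 0 does not show that a gene was silent, so fewer endothelial cells in TGA are not shown. The class 8 against 2 difference of this list differed by -0.84 between TGA and WT. By exact permutation of genotype labels within class, this had p = 0.0306 (the smallest of 19 lists, adjusted 0.582) and did not pass.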
